A study of Mus musculus with 4 samples.

How the data were processed

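RNA from LPS-stimulated mouse bone marrow derived macrophages was measured on 4 one-colour Affymetrix whole-transcript arrays, 2 of control cells with floxed PP2ACα alleles and 2 of cells that also carried Cre. Per the labels' protocols, marrow cells were cultured for 6 days in medium with L-cell supernatant and given 100 ng/ml LPS for 2 hours, and biotinylated cDNA was made from 400 ng of total RNA. Per the series' design text, the authors made the values by robust multi-array averaging (RMA), with background adjustment, normalization and a log2 transformation; the submitters' processing notes name RMA and oligo without versions. The deposited table of log2 values holds 41345 features by 4 arrays, and no column was left unmatched to a sample. Normalization between arrays removes any change of total RNA per cell from such values. Dim features lie near background, where differences are understated, and probes of close paralogs, as in the Oas, Ifi, Slfn, Gbp, Ms4a and Nlrp genes, may read each other's transcripts.

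Genes were named from the platform's probe annotation. Of the features, 23521 had exactly 1 gene symbol, 1814 had several and 16010 had no annotation row and stay unnamed here. The gene IDs of 23328 of the single-symbol features matched the RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. That table was also used for which genes neighbour each other; the files name no genome build, so no coordinates are given. For the 1082 genes with more than 1 feature, the feature with the highest mean over the 4 arrays was used. Of 22180 genes with such a feature, 12542 whose mean reached the median over all deposited features (3.53 log2 units) were tested.

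Groups came from the genotype labels. Knockout was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, not robust, no block), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. All tests were two-sided, except those of gene families, which looked for an excess in each direction separately. The fit had 2 residual degrees of freedom and a prior of 3.51, and the median residual SD was 0.0995 log2 units. A gene is said to rise, fall or be called when it passed. The 1.5-fold cutoff of the series' design text was applied to group means without a test; the text names no test. From 34 gene lists written from textbook knowledge, the 32 with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over those lists. Of these, 12 passed. With the correlation estimated per list, where camera's p-values rest on the 2 residual degrees of freedom, 0 passed. With fry, which tests whether a set moves in a single direction and does not compare it with other genes, 13 passed. Lists share members, such as Slc7a11, Mmp9 and Itgax, and are not independent of one another.

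The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Ppp2ca, Ppp2cb and other PP2A genes that passed, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (leaving out predicted genes, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments), up to 4 members per list, and Tnf, Il6, Il1b, Il10, Ifnb1, Cxcl10 and Ccl5 in any case. It named 143 genes, of which 94 were called. Other genes named were chosen after their values were seen.

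The scripts were tested on simulated data, with 12542 genes and 200 genes changed in each of 20 simulations. Gene means were those of the real arrays, and each SD was drawn at random from limma's fitted prior, with normal noise. The comparison of 2 against 2 arrays recovered 13.4% of genes changed 1.5-fold, 80.1% of those changed 2-fold and 97.2% of those changed 3-fold, and 4.95% of calls were false. The simulated arrays follow the model that limma assumes, so these rates do not test departures from it in the real data. A list of 50 unchanged genes was called in 0 of 20 simulations and one shifted by 0.3 log2 units in 20 of 20; simulated genes varied independently, so this does not test the effect of correlated genes on the lists. Alternatives covered the filter, quantile normalization, median centring, the mean of a gene's features, each array left out, the replicate number as a block, the variance model, array weights, all features as units, the fold cutoff and averaging, and the list test.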

Results

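Whole-transcript expression was measured on 4 arrays of mouse bone marrow derived macrophages, the phagocytes that grow from marrow precursors under macrophage growth factors, after 2 hours with 100 ng/ml of lipopolysaccharide (LPS), the cell wall component of Gram-negative bacteria that Toll-like receptor 4 detects. The control genotype carried floxed alleles of PP2ACα, the alpha catalytic subunit of protein phosphatase 2A encoded by Ppp2ca, with no Cre recombinase. The knockout genotype carried the same alleles with a myeloid Cre, which removes exon 1. The labels write it lyM-Cre and do not spell the name out; it is read here as the widely used line with Cre inserted in the lysozyme gene Lyz2. Each genotype had 2 arrays, labelled as biological replicates, without saying whether they came from separate mice. The number of arrays limits the precision, and the p-values rest on the spread between the 2 arrays of each genotype. All cells had received LPS, so the comparison asks how the LPS-stimulated transcriptome differs without the phosphatase subunit, not how the response to LPS itself differs. The median expression over all features was between 3.50 and 3.57 log2 units on the 4 arrays, and any pair of arrays correlated across features at r = 0.986 to 0.990. The first principal component, with 69.9% of the variance, parted the genotypes, and the second, with 17.5%, parted the control arrays from each other.

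The targeted gene was measured first. Ppp2ca stood at 7.92 ± 0.47 log2 units in control and 3.88 ± 0.69 in knockout macrophages (mean ± SD, n = 2 each), a difference of -4.04 (SE 0.36, limma adjusted p = 0.0076). The arrays read 8.25 and 7.59 in control against 4.36 and 3.39 in knockout, close to the filter level of 3.53, so no fold is given. Of the gene's other features, feature 17262589 differed by -2.24, from 5.31 to 3.07, and feature 17262591 was dim on every array, at 2.63 in control and 2.51 in knockout; where the probes lie relative to the deleted exon was not analysed here. Ppp2cb, the gene of the other catalytic subunit, differed by -0.04 (SE 0.09, adjusted p = 0.83). Among the 29 tested genes of PP2A subunits and regulators, Ppp2ca and Set, which encodes a PP2A inhibitor protein, at -0.50, fell and none rose; the same 2 passed when adjusted over the list alone. Ensa at -0.29 and Ppme1, the gene of the PP2A methylesterase, at -0.27 did not pass, and the list as a whole had a camera adjusted p of 0.62. With control replicate 1 left out, the Ppp2ca difference was -3.71 with an adjusted p of 0.0503. Tested among all 41345 features, without the filter, neither the feature at -4.04 (adjusted p = 0.12) nor that at -2.24 (adjusted p = 0.086) passed.

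**Figure D1:**
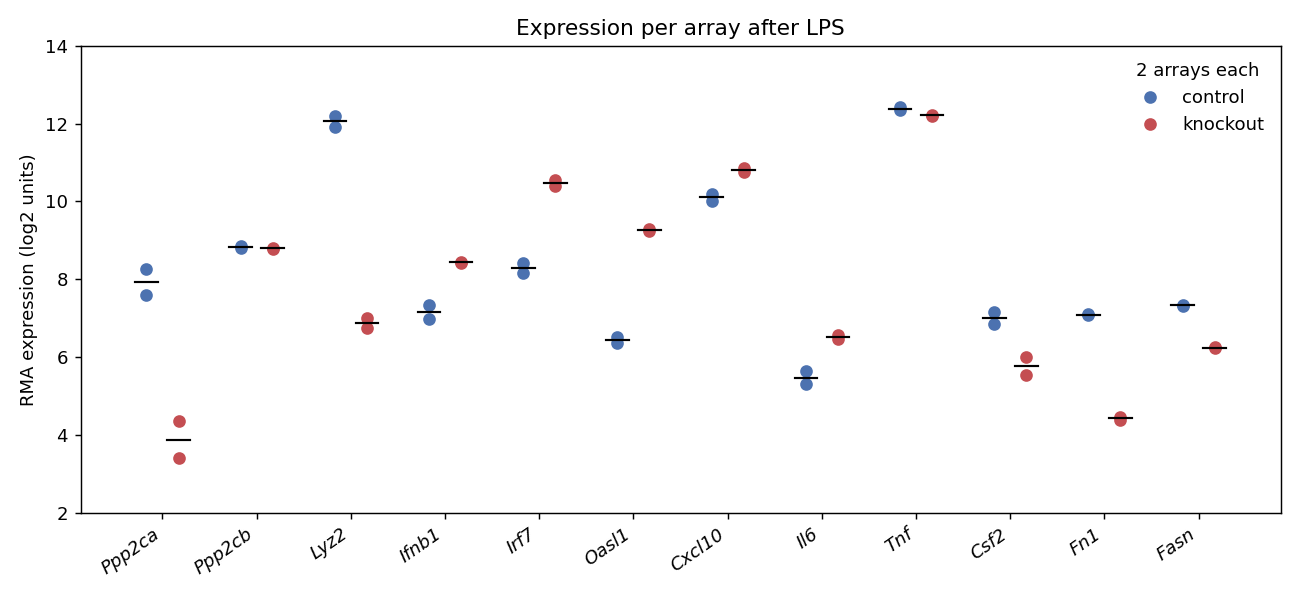
Expression on each array, in RMA log2 units on the vertical axis, for 12 genes on the horizontal axis. Points are single arrays, 2 control (blue) and 2 knockout (red), and black lines are group means. Ppp2ca falls from a mean of 7.92 to 3.88 and Lyz2 from 12.06 to 6.87, while Ppp2cb stays at 8.83 and 8.79.

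Over 12542 tested genes, 852 differed between the genotypes at an adjusted p of 0.05, with 414 higher and 438 lower in knockout. With predicted genes and the other classes of the naming rule left out, the largest rises were in genes known for induction by interferon. Oasl1 rose by 2.82 log2 units (SE 0.10, 7.09-fold), Ifi213 by 2.79, Ifi208 by 2.40, Irf7 by 2.19, Cxcl11 by 2.04, Oas1g by 2.03 and Iigp1 by 2.02. Zbp1, a sensor of Z-form nucleic acids, rose by 1.93, Trim30c by 1.91 and Slfn1 by 1.87. Some of these values lie near the filter level of 3.53, where differences are not exact sizes: the control means were 2.39 for Ifi208, 3.59 for Ifi213 and 3.75 for Iigp1. The largest fall was that of Lyz2, the gene of lysozyme M, from 12.06 ± 0.21 to 6.87 ± 0.17 (SD, n = 2 each), a difference of -5.19 (SE 0.14, adjusted p = 0.00095). After Lyz2 and Ppp2ca came Lrrc32, a surface protein that holds latent TGF-β, at -2.77, the matrix protein fibronectin (Fn1) at -2.66, nestin (Nes) at -2.58 and the integrin gene Itgax at -2.54. Chst11, a chondroitin sulfotransferase, differed by -2.17, Qpct by -2.02, Myo1d by -1.96 and the mitochondrial adenylate kinase Ak4 by -1.88, to a knockout mean of 3.62. Over all tested genes, 55.3% had both knockout arrays on one side of both control arrays, against the 33.3% that chance gives.

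At a cutoff of 1.5-fold on group means, with no test, 657 genes differed, 325 higher and 332 lower, and 547 of them were also called by limma. The series' design text states a list of 1080 genes at this cutoff; over all deposited features, annotated or not, 2273 differed by as much, of which 850 had an annotation. Between the 2 control arrays 268 genes were 1.5-fold apart, and between the 2 knockout arrays 156, whereas the other ways of splitting the 4 arrays into pairs gave 33 and 42. At 2-fold, 100 of the called genes were higher and 73 lower. The number of called genes depended on each array: it was 174 without control replicate 1, 164 without control replicate 2, 96 without knockout replicate 1 and 101 without knockout replicate 2, and 69 of the 852 were kept in all 4 cases. Without pooling the variance across genes, limma called 0 genes, with 2295 at an unadjusted p under 0.05 against 3099 with pooling, and over all features passing the filter 15 of 20673 were called, with 3641 at an unadjusted p under 0.05.

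**Figure D2:**
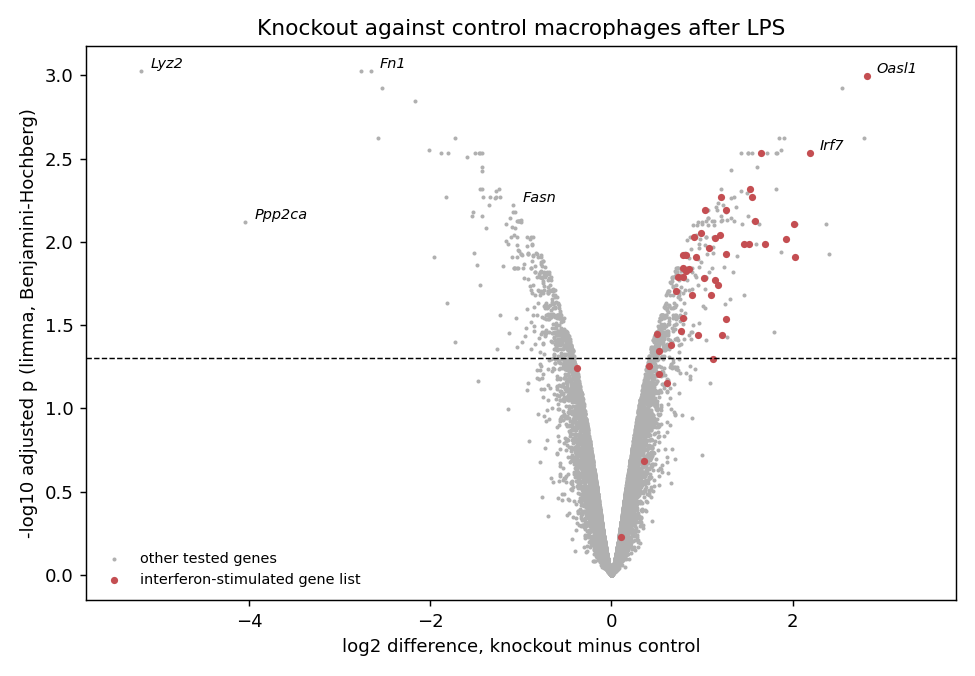
Each point is 1 of the 12542 tested genes, with the log2 difference between knockout and control on the horizontal axis and -log10 of the limma adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05. Red points are the 50 tested genes of the interferon-stimulated list, of which 43 lie above the line on the side of higher expression in knockout.

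Interferon-stimulated genes were higher in knockout macrophages almost throughout the list. Of 50 tested members, 43 rose and none fell, and 47 rose and 1 fell when adjusted over the list alone; the median difference was 1.03 log2 units, or 2.04-fold. Oasl1, Irf7, the transcription factor that amplifies type I interferon production, Oas1g of the 2'-5' oligoadenylate synthetases and the GTPase gene Iigp1 led the list. Ifnb1, which encodes interferon beta, rose by 1.26 (SE 0.14, adjusted p = 0.012), from 7.17 ± 0.25 to 8.43 ± 0.02 (SD, n = 2 each). The camera adjusted p was 1.3e-32 with the preset correlation of 0.01, and adjusted p = 0.26 with an estimated correlation. Genes of antigen presentation and costimulation also shifted upward, with 6 of 19 higher and 0 lower, 7 and 0 adjusted over the list alone, and a median of 0.20 (camera adjusted p = 0.0051; adjusted p = 0.26 with an estimated correlation). They included the peptide transporter Tap1 at 0.89, the immunoproteasome subunit Psmb9 at 0.75, the class I transactivator Nlrc5 at 0.67 and Cd80 at 0.58. Markers of monocytes moved beside these genes without passing as a list: Ms4a4c rose by 1.50, Ccr2 by 0.83 and Ly6c2 by 0.76, while F13a1 fell by 0.79.

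Cytokine levels after LPS differed in both directions. Il6 rose by 1.04 (SE 0.13, adjusted p = 0.017), whereas Tnf differed by -0.17 (adjusted p = 0.30), Il1b by -0.06 (adjusted p = 0.75) and Il10 by -0.23 (adjusted p = 0.32), none of which passed. Of the 27 tested LPS-induced cytokines and mediators, 8 fell and 3 rose, 12 and 4 adjusted over the list alone, with a median of -0.30. The falls were led by tissue factor (F3) at -1.45, endothelin (Edn1) at -1.43, the growth factor Hbegf at -1.38 and Csf2, the gene of GM-CSF, at -1.23; the rises were Il6, Il18 at 0.79 and the iron-scavenging lipocalin Lcn2 at 0.58, of which Il18 was picked for naming after its value was seen. The list went down by camera (adjusted p = 0.00081), with adjusted p = 0.26 with an estimated correlation. Of 20 tested chemokines, 3 rose and 2 fell, 6 and 5 adjusted over the list alone, with a median of -0.00071, a positive mean and a camera adjusted p of 0.95. Cxcl11 rose by 2.04, Ccl12 by 1.02 and Cxcl10 by 0.71, all known as interferon-inducible or monocyte-attracting chemokines, Cxcl14 fell by 0.86 and Ccl6 by 0.75, and Ccl5 differed by 0.68 (SE 0.14, adjusted p = 0.052).

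None of the 5 lists of signalling, feedback, early response and receptor genes passed camera over all 4 arrays with the values as deposited. Among 38 tested genes of the TLR4 signalling list, which also holds other Toll-like receptors, 3 rose, and the camera adjusted p was 0.13. Adjusted over the list alone, 5 rose and 1 fell. The other receptors Tlr9 and Tlr3 rose by 1.57 and 0.88 and the adaptor Tirap by 0.54, while Tlr4 itself differed by 0.42 (limma adjusted p = 0.053). Of 31 genes of negative feedback on NF-kB and cytokine signalling, Peli1 at 0.76 and Otud1 at 0.58 rose and Socs3 at -0.61 fell (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.13), and Nfkbie, at 0.40, did not pass. Of 17 MAPK phosphatase and Sprouty genes, Spry1 at -1.07 and Dusp2 at -0.51 fell, 3 fell and 2 rose adjusted over the list alone, and Dusp16 and Dusp22, at 0.39 and 0.38, did not pass (camera adjusted p = 0.53). Of 36 immediate early and CREB target genes 5 rose, 9 rose and 2 fell adjusted over the list alone, led by Fosb at 0.74, Egr3 at 0.67, Klf2 at 0.56 and Btg2 at 0.55 (camera adjusted p = 0.073, 0.044 with quantile normalization and 0.019 without control replicate 1). Of 37 chemokine and cytokine receptors 3 rose and 2 fell, 6 and 5 adjusted over the list alone, among them Ccr1 at -0.92, Ccr2 at 0.83, Ccr3 at 0.78 and Il13ra1 at -0.52 (camera adjusted p = 0.42).

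The lists of lipid synthesis, glycolysis and hypoxia, and cell cycle genes shifted downward with the preset correlation, and a part of their members fell. Of 25 tested cholesterol and fatty acid synthesis genes, 11 fell and 0 rose, 16 fell adjusted over the list alone, and the median was -0.45 (camera adjusted p = 2.8e-11; adjusted p = 0.26 with an estimated correlation). Fatty acid synthase (Fasn) differed by -1.08, the desaturase Fads2 by -1.03, Fdps by -0.98 and Hsd17b7 by -0.92. Of 21 genes of glycolysis and hypoxia, 6 fell and 0 rose, 9 fell adjusted over the list alone, and all 21 had a negative difference, with a median of -0.30 (camera adjusted p = 4.3e-08; adjusted p = 0.26 with an estimated correlation). These included the phosphofructokinase Pfkl at -0.88, the glucose transporter Slc2a1 at -0.87, Pgam1 at -0.72 and Pgk1 at -0.63. Of 35 cell cycle genes, 12 fell and 0 rose, 19 fell adjusted over the list alone, and the median was -0.38 (camera adjusted p = 1.7e-09; adjusted p = 0.26 with an estimated correlation). Rrm2 of ribonucleotide reductase differed by -1.04, Uhrf1 by -0.88, the replicative helicase subunit Mcm2 by -0.87 and the mitotic kinase Cdk1 by -0.86.

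Of 27 unfolded protein and integrated stress response genes, 7 fell and 1 rose, 10 and 4 adjusted over the list alone, with a median of -0.18 (camera adjusted p = 0.00049; adjusted p = 0.26 with an estimated correlation). The members that fell the most handle amino acids and glutathione: the cystine transporter Slc7a11 at -1.60, the serine synthesis enzyme Psat1 at -1.17, Chac1 at -0.99 and asparagine synthetase (Asns) at -0.97. Ddit3, the gene of the transcription factor CHOP, rose by 0.49 and is named because it was the lone riser. Of 16 NRF2 target genes, 3 fell and 0 rose, 9 fell adjusted over the list alone, with a median of -0.34 (camera adjusted p = 1.4e-05; adjusted p = 0.26 with an estimated correlation). These 3 were Slc7a11, shared with the stress response list, and the glutathione synthesis genes Gclc at -0.94 and Gclm at -0.58. Of 11 heat shock genes none changed, 3 fell adjusted over the list alone, and the camera adjusted p was 0.68; Hspe1 differed by -0.58 and Hspd1 by -0.51. Of 9 LXR target genes, Ch25h at 0.63 and the cholesterol exporter Abcg1 at 0.46 rose, the same number adjusted over the list alone (camera adjusted p = 0.13).

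Fn1 and Itgax, both among the 10 largest falls, belong to the list of matrix and adhesion genes. Of 26 matrix and adhesion genes, 7 fell and 3 rose, 10 and 6 adjusted over the list alone, with a median of -0.12; Fn1, Itgax, Mmp9 at -1.09 and Mmp12 at -1.04 led the falls. The list passed with a camera adjusted p of 0.038 and had adjusted p = 0.61 with an estimated correlation. It also missed the threshold with the stricter filter (0.053), quantile normalization (0.055), median centring (0.067) and camera on ranks (0.17). The same held with control replicate 1 or knockout replicate 2 left out. Of 9 tested osteoclast markers, which include genes of macrophage fusion and acid secretion, 4 fell and none rose, 7 fell and 1 rose adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.00013; adjusted p = 0.26 with an estimated correlation). The proton pump subunit Atp6v0d2 differed by -1.73, the fusion receptor Dcstamp by -1.46, Mmp9 by -1.09 and Ocstamp by -0.60. Of 26 lysosome and phagocytosis genes, Atp6v0d2 fell and Ctsh, at 0.59, rose, with 2 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.68).

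Macrophage identity genes did not shift as a list, with 3 of 25 higher and 3 lower, 6 and 5 adjusted over the list alone (camera adjusted p = 0.69). Siglec1, a sialic acid receptor, rose by 1.21 and the Fc receptor gene Fcgr1 by 0.94, whereas Lyz2 and the scavenger receptor Marco, at -0.86, fell. At the 2 lysozyme genes, written down as a check of the Cre locus and too few for a list test, Lyz1 differed by 1.08 (SE 0.26, adjusted p = 0.071) and Lyz2 fell; adjusted over the list alone, 1 rose and 1 fell. Of 15 alternative activation genes, Arg1 at -0.89 and F13a1 at -0.79 fell, 4 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.17). Of 22 inflammasome and cell death genes, 2 rose and 2 fell, the same numbers adjusted over the list alone: Pmaip1 at 0.88, Mlkl at 0.55, Bcl2l1 at -0.78 and Bcl2 at -0.73 (camera adjusted p = 0.42). None of the 5 tested histone genes changed, 1 rose adjusted over the list alone, and the camera adjusted p was 0.37.

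Markers of other cell types are set beside the 6.79% of all tested genes that were called. Of 10 monocyte markers 3 rose and 1 fell, 5 and 3 adjusted over the list alone (camera adjusted p = 0.17), and of 8 markers of neutrophils and their precursors Lcn2 rose and Mmp8, at -0.84, fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.37). Of 9 dendritic cell markers Bst2, at 0.89, rose and Itgax fell, 3 and 2 adjusted over the list alone, with a median of 0.15 but a mean of -0.12 (camera adjusted p = 0.68). No marker of T and NK cells (4 tested, camera adjusted p = 0.37), B cells (4 tested, 0.35) or fibroblasts and stromal cells (8 tested, 0.83) changed; adjusted over the list alone, 1 T and NK cell marker and 1 B cell marker rose. The 2 tested markers of mast cells, basophils and eosinophils, Gata2 at -0.24 and Prss34 at -0.06, did not pass over all genes or adjusted over the list alone. Of 5 erythroid and megakaryocytic markers Vwf, at -0.88, and Ppbp, at -0.45, fell, 3 fell adjusted over the list alone, and the median was -0.45. The camera adjusted p was 0.026, with 0.37 with an estimated correlation, 0.16 with no filter and 0.061 on ranks. The list also missed the threshold without control replicate 1. Of 3 tested sex-linked genes, all on the Y chromosome, Uty rose by 0.60 and 2 rose adjusted over the list alone. The camera adjusted p of that list was 0.034, with adjusted p = 0.37 with an estimated correlation and 0.067 with no filter. It also missed the threshold without knockout replicate 1.

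**Figure D3:**
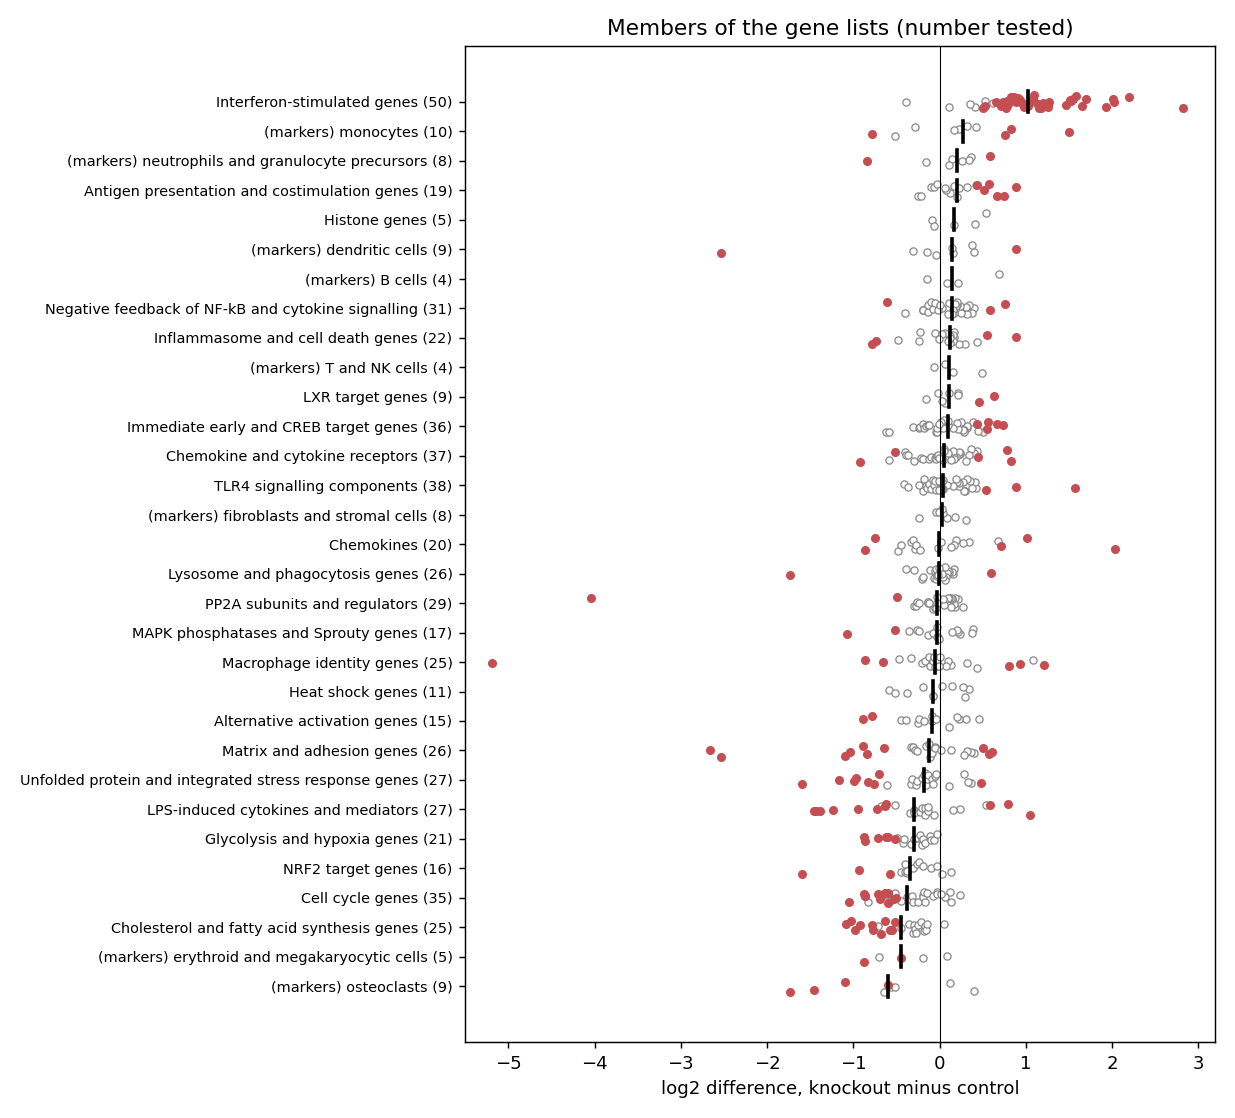
Log2 difference between knockout and control (horizontal axis) for each tested member of 31 gene lists (vertical axis, number tested in brackets). Red points passed the limma test, open points did not, black bars are medians, and the vertical scatter within a list has no meaning. The interferon-stimulated list has the highest median, 1.03, and the osteoclast markers the lowest, -0.60.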

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

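Under the alternatives, planned before the data were seen, no called list or named gene turned direction. The groups of the 94 called named genes did not overlap, so no array left out could turn a sign. Filters, block and variance models change no gene's difference. Directions of other called genes were not compared. The number of called genes (852) was 333 with no filter, 330 of them shared, 312 with the replicate block, 305 of them shared, 1584 with an intensity trend, 15 over all features and 0 without moderation (2295 at an unadjusted p under 0.05); it was 96 to 174 with 1 array left out, where 1 residual degree of freedom is left and the lone array is assumed to vary like the other genotype. It lay between 819 and 1168 with the stricter filter, both scalings, the mean of features, robust moderation and array weights; the share of calls that were higher, 48.6%, was 39.4% with median centring, 53.8% with no filter and with the block, and 52.1% to 68.4% with 1 array left out, the highest (119 higher, 55 lower) without control replicate 1. The 1.5-fold list (657) was 177 at 2-fold, 2273 over all features and 622 to 827 otherwise. Same-numbered replicates deviated from their group means at r = -0.0357 across genes, so no pairing by number showed. The labels do not say whether equal numbers share a preparation. With the block, no list call changed. Each replicate number holds 1 array per genotype, so the block keeps the Ppp2ca difference at -4.04. The Ppp2ca difference lost its call without moderation (-4.04, adjusted p = 0.22), without control replicate 1, and among all features without the filter (adjusted p = 0.12); it ranged from -4.53 to -3.56 with 1 array left out and was -2.14 as the mean of its features.

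With an estimated correlation 0 of the 12 list calls were left. The camera adjusted p was then 0.61 for matrix and adhesion genes, 0.37 for erythroid markers and for sex-linked genes, and 0.26 for the other 9. These p-values rest on the 2 residual degrees of freedom, so the losses do not show that correlation between genes undid the calls. The osteoclast list, with an estimated correlation of -0.037, under the preset 0.01, went from an unadjusted camera p of 2.5e-05 to 0.048. Others of the 12 had higher estimates, up to 0.31 for the interferon-stimulated list. In the other settings the count was 10 to 13, not always of the same lists. Immediate early and CREB target genes gained a call with quantile normalization (0.044) and without control replicate 1 (0.019), alternative activation genes without knockout replicate 2 (0.044) and LXR target genes with fry (0.027). The adjusted p of the erythroid list was 0.16 with no filter, 0.061 on ranks and 0.013 to 0.11 with 1 array left out, and that of the sex-linked list 0.067 with no filter and 0.039 to 0.059 with 1 array left out. That of the matrix list was 0.053 with the stricter filter, 0.055 with quantile normalization, 0.067 with median centring, 0.17 on ranks and 0.023 to 0.12 with 1 array left out. Among the named genes other than Ppp2ca, 60, 57, 68 and 64 lost their call without control replicates 1 and 2 and knockout replicates 1 and 2, 31 with the block, 29 with no filter and 93 without moderation, and 20 calls were kept in all 4 cases of an array left out. Genes called under neither setting counted as the same whatever their sign. Apart from what fewer arrays or more tests bring by construction, the cause was not tested. Signal over background limits dim features.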

Other observations

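Gene families grouped by the letters that open their symbols were examined beyond the fixed lists; this grouping and the genes named here were chosen after the gene table was seen. Of 377 families with at least 5 tested members, 11 held more called genes in 1 direction than chance gives by a hypergeometric test adjusted over 754 tests. That test takes genes as independent, which paralogs with similar probes and shared regulation are not, so its p-values are too small by an unknown amount. The Oas genes (5 of 5 higher), Ifi genes (6 of 11 higher and 1 lower), Slfn genes (5 of 7), Parp genes (5 of 11), Gbp genes (3 of 5) and Ifit genes (3 of 5) overlap the interferon-stimulated list in 3, 3, 2, 1, 2 and 4 members. Outside that list, Ms4a genes rose in 4 of 7 cases, led by Ms4a6b at 1.51 and Ms4a4c at 1.50. Toll-like receptor genes rose in 4 of 10 cases: Tlr9 by 1.57, Tlr5 by 1.28, Tlr3 by 0.88 and Tlr8 by 0.62. Of these, Tlr9 and Tlr3 were members of the fixed TLR4 signalling list, as Ms4a4c was of the monocyte list. Nlrp genes rose in 3 of 6 cases, with Nlrp1b at 1.26. Ifi27, unlike the other called Ifi genes, fell by 0.93.

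Of 13 genes whose symbols open with F and a digit, a stem that mixes coagulation factors with receptors and is no test of coagulation genes, 5 were lower (adjusted p = 0.0065 for the stem). They were the receptor gene F2rl2 at -1.53, tissue factor F3 at -1.45, factor X (F10) at -1.43, factor VII (F7) at -1.14 and F13a1 at -0.79. F3 and F13a1 were also members of fixed lists given above. The Mcm replication helicase family fell in 4 of 10 cases (adjusted p = 0.024). These were Mcm2, Mcm3, Mcm5 and Mcm7, all members of the fixed cell cycle list. Among the 69 calls kept with each array left out, 38 were higher and 31 lower, including Tgfb3 at 1.87, Fcgr4 at 1.85, Rgs16 at -1.80 and the arginine transporter Slc7a2 at -1.43.

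In what follows, the tests of scaling, of the LPS response, of Cre and of Lyz1 were chosen after the results were seen. The predictions for the flanking segments, ATF4 and cell cycle phase were written before those tests were run. The ATF4 and cell cycle phase tests were prompted by falls already seen in the fixed lists on these same arrays. The higher interferon-stimulated genes stayed when the arrays were rescaled, with a list median of 0.99 at its lowest under quantile normalization and median centring. The values had already been normalized, so rescaling could move the list little. Array medians ran only from 3.50 to 3.57, so the shifts left between arrays were too small to give the list's 1.03. A generally stronger LPS response was taken to raise the LPS-induced cytokine list as well, whose median was -0.30, with 8 falls and 3 rises. Levels after LPS were thus not raised throughout that list. All arrays had received LPS, so the response itself was not measured and these values cannot tell whether it was stronger. Cre or loss of Lyz2 cannot be told apart from loss of Ppp2ca, because 0 arrays had low Lyz2 with normal Ppp2ca; that Cre sits in Lyz2 is a reading of the label. Of the 43 called members, 1 lay among the 50 tested genes on either side of Lyz2 or Ppp2ca, and the 43 were spread over 17 chromosomes.

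Lyz2 was lower while its close paralog Lyz1 was not. Probes of Lyz1 that read the Lyz2 transcript would carry the fall over, but Lyz1 differed by 1.08 (SE 0.26, not called). This is the value that raised the question, so it is no separate test. Whether the Lyz1 difference may follow from the loss of Lyz2 or of Ppp2ca stays open, since both were lost on the same arrays.

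The genes called between the genotypes could in part be carried by chromosome segments that flank the targeted loci. Of the 200 nearest tested genes, 19 were called (9.5%), against 6.74% of the others, an odds ratio of 1.45 (95% confidence interval 0.85 to 2.35, Fisher's exact test, p = 0.12). The interval holds both no excess and a doubling, so this stays open, and the 19 make up few of the 852. Both genotypes carried the floxed alleles, so segments flanking Ppp2ca would be shared. That leaves segments at the Cre locus, read here as Lyz2. The test pooled the neighbours of Lyz2 and Ppp2ca, so it cannot decide for the Lyz2 segment alone.

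The falls of Slc7a11, Psat1 and Asns led to the hypothesis of lower expression of amino acid genes among the targets of ATF4, the transcription factor of amino acid deprivation. Of 25 tested ATF4 targets outside the fixed lists, most of them genes of amino acid synthesis, transport and tRNA charging, 9 fell and 1 (Vldlr) rose. The median was -0.42 (unadjusted camera p = 3.7e-07, and 0.030 with an estimated correlation). The fixed lists are given above with adjusted values. Unadjusted and with an estimated correlation, camera gave p = 0.042 for the cell cycle list and 0.043 for the glycolysis list. Of the 25, 21 lay below 0. Members within and outside amino acid handling ranged from Ddit4 at -1.14 and Eif4ebp1 at -0.49 to Slc3a2 at 0.07 and Got1 at 0.25, none of these being called. Of known targets in the fixed lists, picked after their values were seen, Ddit3 rose by 0.49, Trib3 differed by -0.06 and Atf3 by 0.31, and Atf4 itself differed by -0.32 (adjusted p = 0.11). ATF4 activity was not measured, and the Cre confounder applies here too.

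For the lower cell cycle genes, a larger fall of S phase genes than of mitosis genes was tested on members outside the fixed list. The medians of 27 S phase genes and 31 mitosis genes differed by -0.033 log2 units (permutation test over genes, which are not independent replicates, p = 0.70). This was under the 0.1 set beforehand as the bound against the idea. Of the S phase genes 23 lay below 0 and 6 fell, and of the mitosis genes 21 lay below 0 and 5 fell. In both sets 0 rose. The test compared medians alone, so it does not cover other differences between the 2 sets.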
